A study of Mus musculus with 6 samples.

How the data were processed

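The study measured polyA-selected RNA of primary mouse BMDM in 6 libraries, 3 wild-type and 3 labelled Txn1 KO. Libraries were made with the NEBNext Ultra II RNA kit after addition of ERCC spike-ins, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b and DESeq2 (version not given in the sources used here) were used with the mouse build GRCm38 (mm10). The read counter, its use of strand and the gene annotation are not given in the sources used here.

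The deposited table lists 14005 gene identifiers with a value per library, a log2 fold change, a p-value and an adjusted p-value. The per-library signal is the authors' read count divided by 1 size factor per library, as the values show: each deposited value is a whole multiple of its library's smallest step, for 100% of values in each library at a tolerance of 0.01 reads. The step, which is the value of 1 read, ran from 0.777 to 1.35 normalized counts. The log2 fold changes and the p-values were computed by the authors, and the deposited adjusted p is the Benjamini-Hochberg value over the listed genes that have a p, of which there are 13985. The lowest mean of a listed gene is 9.28 normalized counts, so genes below that were not analysed here, and no ERCC rows are listed. A further table of gene ontology terms named in the labels was not used here. The columns of the libraries labelled Txn1 KO were matched to samples by the group and number in the column name. The control columns name only BMDM and a number, and were taken as the wild-type samples because these are the only other group. Every column name also holds "Phi", which the labels do not explain. No per-sample column was left unused.

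Whole reads recovered from the steps summed to 29716640, 38726953 and 35988877 in wild type and 25939608, 31127228 and 22508616 in the libraries labelled Txn1 KO. With 3 reads as the floor, the smallest level told from 0 was 2.33 to 4.04 normalized counts, which covers counting error only. The gene with the most reads, Psap, took 2.32% to 2.57% of a library. Within a group, pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 6.14 to 29.6), unlike 1 library listed under different names. This says nothing on whether the samples came from separate animals or cultures.

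The design foresaw a count test for raw counts and limma for normalized values. Since the deposited values are normalized, the main test was limma 3.58.1 in R 4.3.3 with a trended prior on log2(normalized count + 1), over the 13977 genes with a mean of at least 10, which left out 28. Log2 changes and the 2-fold threshold are on that scale, which understates the change of low genes; the other fold changes of genes are ratios of mean normalized counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 30 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation; 13 lists passed at the preset value and 0 with the estimate. List members were counted at the adjusted p over all genes and adjusted over the list alone. Symbols came from the deposited table. Positions came from GENCODE M21 on GRCm38, in which 13950 of the tested genes had a match.

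The lists, the main test, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Txn1, Lyz2 and the NLRP1 list, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 and no overlap between groups, and from each other list up to 4 called members with the smallest p, or 2 members where none is called. Members named to spell out a small count (such as those of a list that did not pass), and Alb, Eif2s3y and Xist, were chosen after their values were seen. Some genes that the rule or these counts would name are not reported here. Alternatives were other thresholds, pseudocounts and filters, leaving out each library, the replicate number as a block, the authors' statistics, leaving out the chromosomes of Txn1 and Lyz2, and other settings of camera. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom on the recovered reads, a fit without the 2 libraries with liver transcripts, and the other lists without members of the NRF2 list. On the recovered reads edgeR called 3047 genes, of which 2942 were also called by limma.

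The scripts were tested on simulated libraries, 3 against 3, with 200 of the genes changed and 13860 tested. At a log2 change of 0.5, 66.3% of the changed genes were recovered, and at 1, 79.4%. Of 156 calls 14 were false. A list shifted by 0.5 was detected, and 1 other list was called. Genes were drawn independently of each other, so this simulation cannot show how the list test fares where list members vary together.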

Results

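RNA from mouse bone marrow-derived macrophages (BMDM), primary macrophages grown from bone marrow, was sequenced after polyA selection in 2 groups of 3 libraries. The controls were wild-type C57BL/6J cells. The other group was labelled Txn1 KO: a Txn1 allele combined with a Cre recombinase knocked into Lyz2, a gene that macrophages express at a high level, so that the knock-in interrupts Lyz2 itself. Txn1 encodes thioredoxin-1, the cytosolic disulfide reductase. The stated purpose was to learn how loss of this protein affects expression of NLRP1 inflammasome genes. Wild-type replicates 1 to 3 held 29716640, 38726953 and 35988877 reads in the listed genes, and the libraries labelled Txn1 KO held 25939608, 31127228 and 22508616. The first principal component took 40.0% of the variance and separated the groups. The second took 29.3% and set wild-type replicate 1 and the Txn1 KO library 3 apart from the other 4. These 2 libraries also carried transcripts of liver genes, with Alb (albumin) at 642.9 and 580.0 normalized counts against at most 0.838 in the other 4. The labels give both groups as pooled male and female. All 7 listed Y-linked genes fell in the libraries labelled Txn1 KO (median log2 change -1.02), for example Eif2s3y from 1086 ± 49.2 to 553.6 ± 21.5 normalized counts (SD, n = 3 each). Xist, expressed from the inactive X chromosome, rose by 0.29 ± 0.078 (log2, SE; adjusted p = 0.0129, limma). Both differences follow the same split of the libraries as every comparison given here.

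Txn1 itself (ENSMUSG00000028367, chromosome 4, 57943373 to 57956411, minus strand, GRCm38) was not lower in the libraries labelled Txn1 KO. It had 12580 ± 532 normalized counts in wild type and 12349 ± 367 in the other group (SD, n = 3 each), a log2 change of -0.03 ± 0.037 (SE; limma adjusted p = 0.686). The 95% interval of the ratio ran from 93.0% to 104% of wild type, and the log2 change was 0.01 without wild-type replicate 1. The values are sums over the whole gene and the labels do not name the deleted part, so reads outside it cannot show a deletion. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), which encodes lysozyme, fell from 364408 ± 3550 to 3118 ± 1281 normalized counts, a log2 change of -6.96 ± 0.19 (limma adjusted p = 1.94e-13). The 3 libraries labelled Txn1 KO had 4327, 3251 and 1775 normalized counts of Lyz2. Lyz2 thus follows the group labels in all 6 libraries, while the whole-gene level of Txn1 did not tell the groups apart. By the labels, each library labelled Txn1 KO carries both the Cre insertion and the Txn1 allele in every comparison. No library with Cre alone was analysed here.

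**Figure D1:**
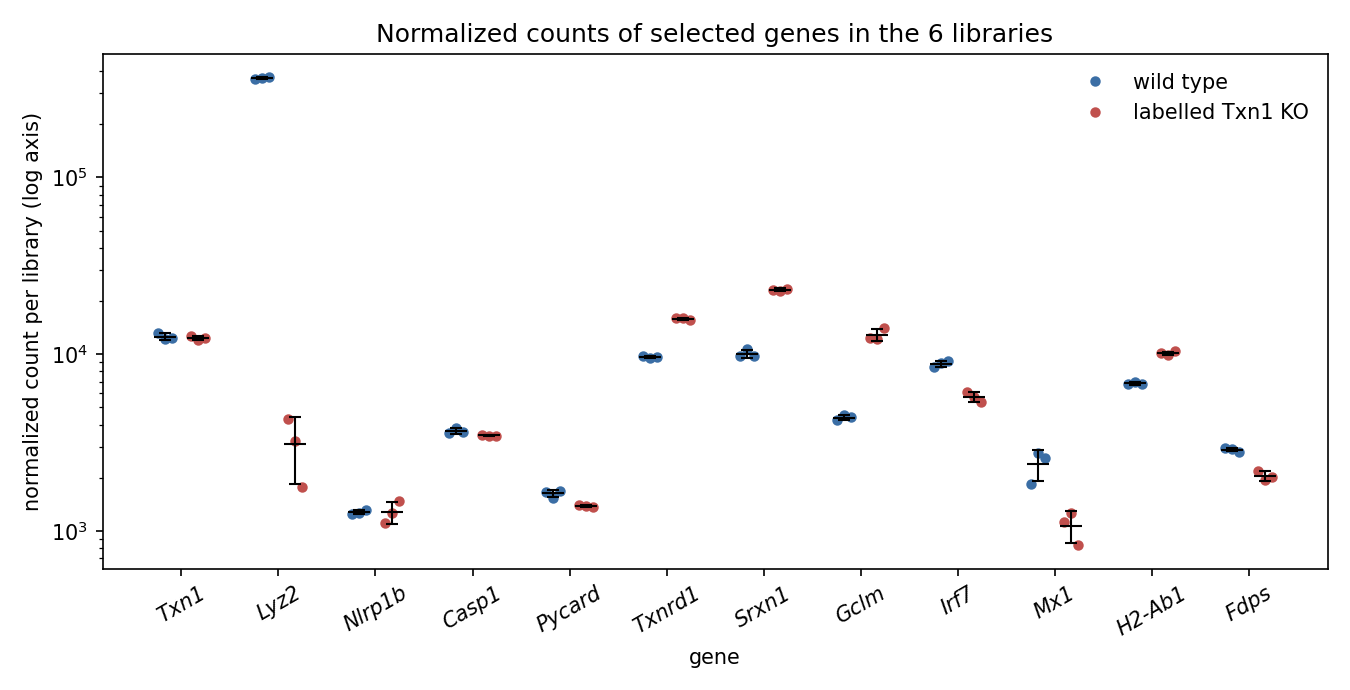
Normalized counts (log axis) of 12 genes in each of the 6 libraries, with points for single libraries, a black bar for the mean and whiskers for 1 SD. Txn1 overlaps between the groups, Lyz2 falls from a mean of 364408 to 3118, and the other genes shown are members of the gene lists described in the text.

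Of 11 measured genes of the NLRP1 inflammasome and its regulators, 10 did not pass the test between the groups and 1 did. Pycard (ENSMUSG00000030793, chromosome 7, 127989708 to 127993867), which encodes the adaptor ASC, fell from 1632 ± 79.0 to 1383 ± 13.4 normalized counts (log2 -0.24 ± 0.048, limma adjusted p = 0.00167, lower in 3 of 3 libraries). The sensor gene Nlrp1b (chromosome 11, 71153102 to 71230733) had 1282 ± 35.9 normalized counts in wild type and 1283 ± 185 in the libraries labelled Txn1 KO. Its log2 difference was -0.01, with a 95% interval of -0.17 to 0.15, and it turned positive without wild-type replicate 3 (0.01) or Txn1 KO library 1 (0.09). Nlrp1a had a log2 difference of -0.02 (SE 0.11; 0.07 without Txn1 KO library 1), and the pseudogene Nlrp1c-ps, near-identical in part to its neighbours and so uncertain, one of 0.27 (SE 0.12, limma adjusted p = 0.120). Casp1, the protease of the inflammasome, and Gsdmd, the pore-forming protein it cleaves, both had a log2 difference of -0.08 (limma adjusted p = 0.162 and 0.175). Gsdmd passed the test at -0.12 (limma adjusted p = 0.0428) when the 2 libraries with liver transcripts were left out. Dpp8 and Dpp9, whose proteins hold NLRP1 inactive, differed by -0.06 and -0.12. Il18 differed by -0.11. Il1b was near the floor of detection, with 8.42 ± 2.88 normalized counts in wild type and 14.9 ± 2.39 in the libraries labelled Txn1 KO (limma adjusted p = 0.248). Adjusted over the list alone, the count was the same, 1 gene. As a list these genes did not rank apart from the others (camera adjusted p = 0.301, and adjusted p = 0.433 with an estimated correlation). The test pointed down, as did the list's median (-0.06), while its mean was 0.03.

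Other inflammasome sensors and pyroptosis genes had 7 members that rose and 1 that fell among 19 measured, with the same counts adjusted over the list alone. Mefv, which encodes the sensor pyrin, rose from 133.8 ± 16.8 to 299.5 ± 40.5 normalized counts (log2 1.16, limma adjusted p = 3.06e-06). Il18bp, the secreted antagonist of IL-18, rose by 0.47 and Ninj1, which encodes the protein of membrane rupture, by 0.28. Naip5, a sensor of flagellin with near-identical neighbours that can share its reads, rose by 0.21, and its call was lost without wild-type replicate 2 (limma adjusted p = 0.0567) and without the 2 libraries with liver transcripts (limma adjusted p = 0.0615). Il1rn, the interleukin-1 receptor antagonist, was the member that fell (-0.21). The list test did not pass (camera adjusted p = 0.0931).

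Across all genes, 3001 of 13977 tested passed the limma test at an adjusted p under 0.05, with 1607 higher and 1394 lower in the libraries labelled Txn1 KO. Of these, 311 changed at least 2-fold, 216 of them upward and 95 downward. The groups did not overlap for 97.5% of the called genes. That share was 36.2% over all tested genes, where chance gives 10%. Without wild-type replicate 3, 891 genes were lower. The authors' deposited table calls 2691 genes, 1450 of them higher, and 2659 were called in both, all in the same direction. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

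The 10 largest rises among called genes with a mean of at least 50 held 4 processed pseudogenes (Gm7993, Rps13-ps1, Rps15a-ps7 and Gm6472), copies that can share reads with their parent genes and are uncertain. Of the protein-coding genes, Tnfsf4, which encodes the T cell co-stimulator OX40L, rose from 2.91 ± 2.54 to 99.2 ± 15.5 normalized counts (log2 5.02 ± 0.53, limma adjusted p = 2.34e-06). Plekha7, which encodes a protein of epithelial junctions, rose from 5.13 to 160.2 (log2 4.85 ± 0.35). B3gnt7, a glycosyltransferase gene, rose from 23.9 to 294.1 and Gdpd3, a phosphodiesterase gene, from 111.5 to 785.5 normalized counts. Trim34b and Zfp979, members of families with close copies, rose by 3.56 and 2.82 and are uncertain for that reason. Besides Lyz2, the 10 largest falls included the non-coding A530040E14Rik (log2 -2.70) and, on the same chromosome 1, Sp140 and Sp110, nuclear body proteins of the Sp100 family. Sp110 fell from 3354 ± 121 to 600.8 ± 76.8 normalized counts (log2 -2.49 ± 0.070, limma adjusted p = 2.26e-13) and Sp140 from 1453 ± 130 to 254.3 ± 23.5 (log2 -2.51). A530040E14Rik is annotated as antisense and the counting's use of strand is not given in the sources used here, so its value is uncertain. Ibsp, a bone matrix gene, fell from 90.2 to 18.2 (log2 -2.58) and Grem1, a secreted BMP antagonist, from 111.2 to 28.8 normalized counts, alongside the stromal markers described further on. Mmp9 (log2 -1.94), Cxcl10 (-1.86), Slfn1 (-1.76) and the pseudogene Gm1966 (-1.70) completed the 10.

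Targets of NRF2, the transcription factor of the oxidative stress response, rose together. Of 30 measured, 27 rose and 0 fell in the libraries labelled Txn1 KO, with the same counts adjusted over the list alone, and the median log2 change was 0.76 (camera adjusted p = 5.44e-40, and adjusted p = 0.0729 with an estimated correlation). Gsta3, a glutathione transferase, rose 5.17-fold from 358.3 ± 12.9 to 1853 ± 133 normalized counts (SD, n = 3 each, limma adjusted p = 1.94e-13). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose 2.94-fold from 4381 ± 155 to 12891 ± 1032 (limma adjusted p = 6.29e-13). Srxn1, which encodes sulfiredoxin, rose 2.30-fold, and Cat, which encodes catalase, rose 2.14-fold. The 3 members not called were Tkt (0.04), Ftl1 (0.01) and Fth1 (-0.07).

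Glutathione genes moved in the same direction, and 6 of them (Gclc, Gclm, Gsr, Slc7a11, Gstm1 and Gstp1) stand in the NRF2 list too. Of 23 measured, 11 rose and 0 fell, against 13 and 0 adjusted over the list alone (camera adjusted p = 1.16e-10, and adjusted p = 0.102 with an estimated correlation; 0.00195 over the 17 outside the NRF2 list). Gclc, the catalytic subunit for the first step, rose from 1547 ± 23.0 to 3535 ± 161 normalized counts, and Gsr, glutathione reductase, from 2458 ± 69.4 to 5215 ± 324. Slc7a11, the cystine transporter, rose 2.87-fold (log2 1.52 ± 0.064, limma adjusted p = 2.15e-11).

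Within the thioredoxin system the changes were split. Of 22 measured members 7 rose and 3 fell, against 8 and 3 adjusted over the list alone. Those that rose included Prdx6 and Prdx1, peroxiredoxins that reduce peroxides (log2 1.29 and 0.96), Srxn1 (1.20) and Txnrd1, the cytosolic thioredoxin reductase. Txnrd1 went from 9649 ± 152 to 15894 ± 194 normalized counts (log2 0.72 ± 0.031, limma adjusted p = 3.11e-11). The 3 that fell were Txnip, which encodes a thioredoxin-binding protein (-0.32), Msra (-0.24) and Txndc12 (-0.23). The list did not pass its test (camera adjusted p = 0.134), though it did, upward, without the 2 libraries with liver transcripts (0.0150). Its median was -0.04, while its mean of 0.17 and its test pointed up. Txnrd1, Prdx1 and Srxn1 stand in the NRF2 list too, and without them the test pointed down (camera adjusted p = 0.837).

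In the pentose phosphate and NADPH list 6 of 17 rose and 2 fell, against 7 and 3 adjusted over the list alone (camera adjusted p = 0.00432, and adjusted p = 0.109 with an estimated correlation). Of the 17 members, 5 (Tkt, Taldo1, Pgd, G6pdx and Me1) stand in the NRF2 list too, and without them the list did not pass (2 of 12 rose and 2 fell, camera adjusted p = 0.570). Taldo1 and Pgd, enzymes of the pentose phosphate pathway, rose by 0.73 and 0.64 (log2), Me1, malic enzyme, by 0.87 and Nnt, the mitochondrial transhydrogenase, by 0.54. Nnt carries a known deletion in C57BL/6J, the strain of the wild-type cells. Whether a difference of strain lies behind its rise was not tested. In the metal list 8 of 14 rose and 0 fell, against 8 and 1 adjusted over the list alone (camera adjusted p = 8.99e-06, and adjusted p = 0.101 with an estimated correlation), and it passed without the 3 members of the NRF2 list (Hmox1, Fth1 and Ftl1; 7 of 11 rose, 1.16e-05). Slc40a1, which encodes the iron exporter ferroportin, rose from 1813 ± 194 to 5310 ± 441 normalized counts (log2 1.55, limma adjusted p = 3.06e-11). Slc11a1, the phagosomal metal transporter, rose by 0.70, Hmox1, heme oxygenase, by 0.85 and Slc30a1, a zinc exporter, by 0.50.

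**Figure D2:**
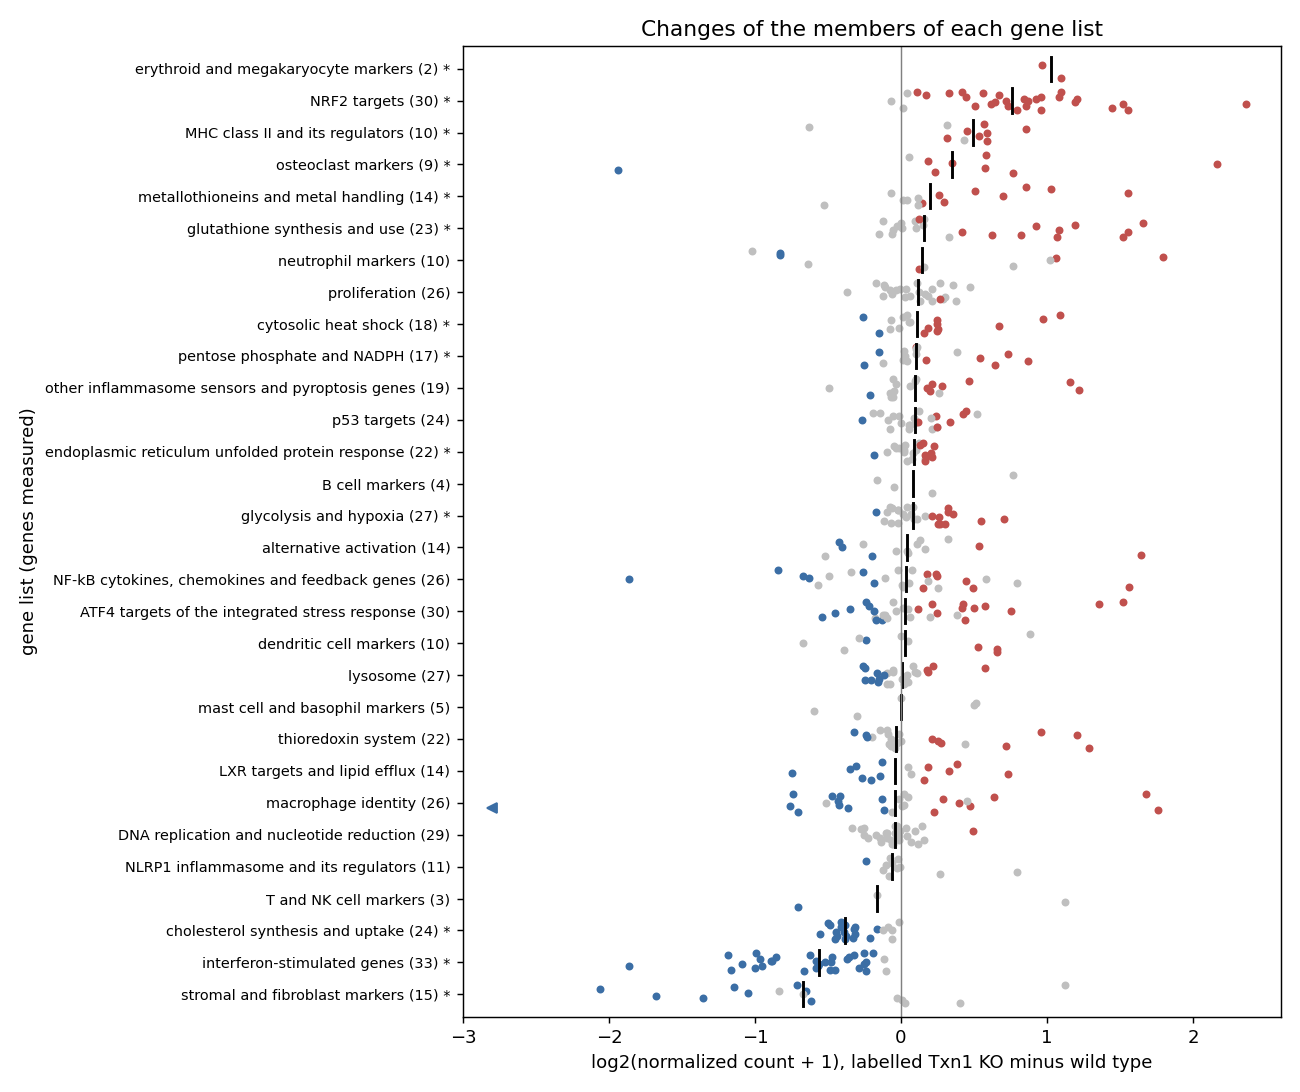
Log2 change of each measured member of the 30 gene lists, as libraries labelled Txn1 KO minus wild type, with lists in the order of their median (black bar) and an asterisk for a camera adjusted p under 0.05 at the preset correlation. Red and blue points passed the limma test upward and downward, gray points did not, and the blue triangle at the left edge is Lyz2, whose change of -6.96 lies off the scale; NRF2 targets have a median of 0.76 and interferon-stimulated genes one of -0.56.

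Interferon-stimulated genes were lower in the libraries labelled Txn1 KO. Of 33 measured, 31 fell and 0 rose, against 32 and 0 adjusted over the list alone, with a median log2 change of -0.56 (camera adjusted p = 6.62e-24, and adjusted p = 0.203 with an estimated correlation, whose estimate was 0.740). Irf7, a transcription factor of the interferon response, fell from 8855 ± 339 to 5746 ± 397 normalized counts (log2 -0.63 ± 0.045, limma adjusted p = 2.07e-08). Mx1, an antiviral GTPase, fell from 2398 ± 483 to 1072 ± 219 (log2 -1.16), and Ifit1, which binds viral RNA, fell from 4280 ± 635 to 2214 ± 323 (log2 -0.95). Zbp1, a sensor of Z-form nucleic acids, fell to 0.678 of its wild-type level. Oas2 (-0.10) and Oas3 (-0.12) were the 2 members not called. The stromal markers, with a median of -0.67, were lower in the same libraries.

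Cytokine, chemokine and feedback genes of NF-kB went both ways, with 7 of 26 higher and 6 lower, against 8 and 8 adjusted over the list alone. Cxcl2, a chemoattractant for neutrophils, rose from 74.2 ± 5.77 to 225.1 ± 54.7 normalized counts (log2 1.56, limma adjusted p = 2.61e-06) and Tnfaip2 rose by 0.49. Ccl4 and Ccl5, chemokines for monocytes and T cells, fell (-0.84 and -0.63). The list did not pass (camera adjusted p = 0.940). Its median of 0.03 and its test pointed up while its mean was -0.03.

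Genes of MHC class II antigen presentation rose. Of 10 measured, 7 rose and 0 fell, with the same counts adjusted over the list alone (median log2 0.50, camera adjusted p = 2.29e-08, and adjusted p = 0.0729 with an estimated correlation). Cd74, the invariant chain, rose from 19842 ± 1015 to 29870 ± 152 normalized counts (log2 0.59 ± 0.036, limma adjusted p = 2.57e-09). The chains H2-Ab1, H2-Aa and H2-Eb1 rose by 0.57, 0.54 and 0.59. H2-Oa (0.43), H2-DMb2 (0.31) and H2-Ob (-0.63) did not pass. Among dendritic cell markers 3 of 10 rose and 1 fell, also when adjusted over the list alone: Itgax, which encodes CD11c, rose from 3525 ± 139 to 5568 ± 372 normalized counts (log2 0.66), Batf3 by 0.66 and Ccr7 by 0.53, and Bst2, which is an interferon-stimulated gene too, fell by 0.24 (log2). That list did not pass (camera adjusted p = 0.302).

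Markers of macrophage identity were mixed. Of 26 measured gene identifiers, 7 rose and 11 fell, against 8 and 11 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0850), though it did, downward, without wild-type replicate 2 (0.0307), Txn1 KO library 3 (0.0315) or both libraries with liver transcripts (0.0201). Lyz2, which the Cre knock-in interrupts, is among the 11 that fell and stayed in each of these tests. The list, with a median of -0.04 and a mean of -0.23, was not tested without Lyz2. Apart from Lyz2, the falls with the smallest p were C1qb and C1qa, chains of complement C1q, at -0.74 and -0.76, and Fcgr1, the high-affinity IgG receptor, at -0.71. C1qb went from 31500 ± 985 to 18894 ± 459 normalized counts (limma adjusted p = 5.13e-11). In the list of alternative activation 2 of 14 rose and 3 fell, also when adjusted over the list alone. Egr2 rose by 0.53, and Mrc1, which encodes the mannose receptor, Klf4 and Pparg fell (-0.43, -0.40 and -0.20). That list did not pass (camera adjusted p = 0.961), with median and mean above 0 and a test that pointed down.

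Cholesterol synthesis and uptake genes fell. Of 24 measured, 19 fell and 0 rose, against 20 and 0 adjusted over the list alone, with a median log2 change of -0.38 (camera adjusted p = 1.13e-16, and adjusted p = 0.102 with an estimated correlation). Fdps, which encodes farnesyl diphosphate synthase, fell from 2889 ± 68.7 to 2048 ± 129 normalized counts (log2 -0.50 ± 0.047, limma adjusted p = 5.76e-07). Sqle and Msmo1, enzymes of the later pathway, changed by -0.48 and -0.41. The other 5 members did not pass the test. LXR targets and lipid efflux genes went both ways, with 5 of 14 higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.396). Scd1, a fatty acid desaturase, fell from 1462 ± 54.7 to 871.4 ± 50.8 normalized counts (log2 -0.75), Pltp and Plin2 changed by -0.31 and -0.27, and Mylip rose by 0.38.

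In the glycolysis and hypoxia list 10 of 27 rose and 1 fell, against 12 and 1 adjusted over the list alone (median log2 0.08, camera adjusted p = 0.00239, and adjusted p = 0.109 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose from 1830 ± 23.4 to 2988 ± 53.3 normalized counts (log2 0.71 ± 0.040, limma adjusted p = 8.10e-10). Aldoa, Pgk1 and Pkm, glycolytic enzymes, rose by 0.27, 0.26 and 0.25. The member that fell was Ldha, lactate dehydrogenase (-0.17). Among lysosome genes 4 of 27 rose and 8 fell, against 5 and 10 adjusted over the list alone (camera adjusted p = 0.362). Ctsk rose by 0.57, and Grn and Hexa fell (-0.26 and -0.21). The median of this list was 0.01, while its mean of -0.01 and its test pointed down.

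Of 18 cytosolic heat shock genes 9 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.306 with an estimated correlation). The chaperone gene Hspa1a, which shares reads with its copy Hspa1b, rose from 116.6 ± 8.08 to 229.9 ± 15.1 normalized counts (log2 0.97), Hsp90aa1 and Hsp90ab1 both rose by 0.25, and Fkbp4 (-0.26) and Ahsa1 (-0.15) fell. In the endoplasmic reticulum unfolded protein response 8 of 22 rose and 1 fell, against 12 and 2 adjusted over the list alone (median log2 0.09, camera adjusted p = 0.00968, and adjusted p = 0.109 with an estimated correlation). The chaperone Hsp90b1 rose by 0.17 and Syvn1, a ubiquitin ligase of this compartment, by 0.22. Among ATF4 targets 11 of 30 rose and 8 fell, against 12 and 9 adjusted over the list alone, with no shift of the list (camera adjusted p = 0.418). Slc7a11, which is also an NRF2 target, rose, Slc3a2 and Cebpb rose by 0.42 and 0.75, and Ddit3, which encodes CHOP, fell from 2258 ± 110 to 1650 ± 77.6 normalized counts (log2 -0.45). Of 24 p53 targets 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.134). Plk3 rose by 0.44, Trp53inp1 by 0.34 and Sesn2 by 0.24, and Ei24 fell by 0.26 (log2). The call of Sesn2 was lost without any 1 of the 3 wild-type libraries or without Txn1 KO library 2, where its limma adjusted p was 0.0759, 0.0545, 0.0733 and 0.152. Its log2 change was 0.16 without Txn1 KO library 2.

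Proliferation and DNA replication genes did not move as lists (camera adjusted p = 0.281 and 0.302). In each, 1 gene rose, of 26 and 29 measured, and 0 were called adjusted over the list alone. Mki67, a marker of cycling cells, rose by 0.27 (limma adjusted p = 0.0471), and this call was lost when any library other than wild-type replicate 1 was left out, with a limma adjusted p of 0.0690 to 0.232, the highest without wild-type replicate 2 (log2 0.17). The authors' deposited table gives it an adjusted p of 0.0720. Rrm2, a subunit of ribonucleotide reductase, an enzyme that thioredoxin can reduce, rose by 0.49 (limma adjusted p = 0.0157), and its call was lost without wild-type replicate 2 (0.0597), wild-type replicate 3 (0.103) or Txn1 KO library 1 (0.0544).

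Markers of other cells that a marrow culture can hold did not all move alike. Stromal and fibroblast markers were lower in the libraries labelled Txn1 KO: 8 of 15 fell and 0 rose, also when adjusted over the list alone (median log2 -0.67, camera adjusted p = 4.40e-04, and adjusted p = 0.311 with an estimated correlation). Col1a2, a collagen chain, fell from 730.6 ± 46.3 to 290.4 ± 76.1 normalized counts, Dcn, decorin, from 351.0 ± 9.71 to 165.2 ± 53.5 and Pdgfra, a receptor of mesenchymal cells, fell by 1.68 on the log2 scale. Fn1, fibronectin, fell as well (log2 -0.62, and -0.38 without the 2 libraries with liver transcripts). Of 9 osteoclast markers 7 rose and 1 fell, also when adjusted over the list alone (median log2 0.35, camera adjusted p = 8.83e-05, and adjusted p = 0.101 with an estimated correlation). Acp5, tartrate-resistant acid phosphatase, rose by 0.77, Dcstamp, a gene of cell fusion, by 0.58 and Ctsk, the collagen-degrading cathepsin K, by 0.57. Mmp9 fell from 182.6 ± 28.4 to 48.1 ± 15.9 normalized counts, and Nfatc1 (0.06) was not called. The 2 measured erythroid and megakaryocyte markers, Pf4 (log2 0.96) and Itga2b (1.10), both rose, also when adjusted over the list alone (camera adjusted p = 0.00968, and adjusted p = 0.132 with an estimated correlation). Both are used as markers of megakaryocytes, at 296.8 and 26.4 normalized counts in wild type. The values do not tell which cells carried them. The call of Itga2b was lost without wild-type replicate 3 (limma adjusted p = 0.0666) or Txn1 KO library 2 (0.0796).

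Neutrophil markers had 3 of 10 higher and 2 lower, against 4 and 2 adjusted over the list alone (camera adjusted p = 0.301). Mmp8 rose from 390.4 ± 30.7 to 815.8 ± 51.4 normalized counts, the receptor gene Cxcr2 rose from 13.3 to 49.4, Csf3r rose by 0.12 (log2), and S100a9 and Ngp fell, both at -0.83. The call of S100a9 was lost without wild-type replicate 2 (limma adjusted p = 0.0583). That of Csf3r was lost without any 1 library other than Txn1 KO library 1 (limma adjusted p = 0.0606 to 0.117). It was lost too without the 2 libraries with liver transcripts (limma adjusted p = 0.212), where the log2 change was 0.081. Of 4 B cell markers none passed, adjusted over the list alone or not: Cd22 differed by 0.21 and Igkc by 0.77 (limma adjusted p = 0.120 and 0.229, camera adjusted p = 0.652). Of 3 T and NK cell markers Cd4 fell (log2 -0.70), also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.362, pointing down as its median of -0.17 did, with a mean of 0.09). Thy1, among these 3, had 99.7 normalized counts in Txn1 KO library 1 and at most 10.1 in the other libraries. That mean leans on this library. Of 5 mast cell and basophil markers none passed, adjusted over the list alone or not, with Gata2 at 0.52 and Hdc at -0.60 (limma adjusted p = 0.393 and 0.395, camera adjusted p = 0.961).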

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

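The edgeR, DESeq2 and voom fits, the fit without the 2 libraries with liver transcripts and the lists without NRF2 members were chosen after the data were seen; the rest were planned. At an adjusted p of 0.01 limma called 1833 genes (1024 higher, 809 lower), and with at least a 2-fold change 311 (216 higher, 95 lower), which moved the share of higher genes from 53.5% to 69.5%; both are stricter by construction. Leaving out 1 library at a time gave 2087 to 2816 called genes, 1196 to 1513 higher and 891 to 1303 lower, with the lowest number of lower genes without wild-type replicate 3; these fits have fewer samples. Without the 2 libraries with liver transcripts 2928 genes were called, 2446 of them shared with the 3001 of all 6 libraries. The count stayed within 1.5 times in all other alternatives run, from 2675 to 3793, and no shared call changed direction. With the replicate number as a block 2675 genes were called, 2639 of them shared, and Csf3r was the 1 named gene that did not pass (limma adjusted p = 0.0596). Same-numbered libraries had correlations of deviations from the group mean of -0.27, 0.14 and -0.33, and not every library correlated best with its own number. Wild-type replicate 1 and Txn1 KO library 3 correlated at 0.43. A difference shared by these 2 libraries could hide a pairing by number, so these correlations cannot exclude it.

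With an estimated inter-gene correlation, 0 of 30 lists passed in camera (13 at the preset value). The adjusted p was 0.0729 for NRF2 targets, 0.203 for interferon-stimulated genes, 0.0729 for MHC class II and 0.102 for cholesterol genes, and the cause was not tested. Of the other settings, a preset of 0.05 passed 11 lists (heat shock 0.0829 and unfolded protein response 0.0632 lost), ranks 12 (erythroid and megakaryocyte markers 0.0593 lost) and the log2 fold change as statistic 9, of which 8 were among the 13 (heat shock 0.229, unfolded protein response 0.756, glycolysis 0.446, pentose phosphate 0.269 and osteoclast markers 0.0873 lost, macrophage identity 0.0113 gained). The macrophage identity list holds Lyz2 (log2 -6.96), the gene that the Cre knock-in interrupts, and was not tested without Lyz2. Without members of the NRF2 list in the other lists 12 passed (pentose phosphate 0.570 lost). The replicate block and the fits without 1 library kept all 13.

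Of 126 named genes, 123 had the same direction in every setting that gave them a value (Txn1, Nlrp1a and Nlrp1b, which were not called, did not) and, leaving aside the stricter thresholds, 105 of the 112 called genes were called in each such setting; the fit without the chromosomes of Txn1 and Lyz2 gave a value for 106 named genes and edgeR with a mean of at least 50 for 119. The 7 that lost a call were Mki67, Rrm2, Sesn2, Csf3r, Naip5, S100a9 and Itga2b, and the cause was not tested. Scaling on ERCC spike-ins and the alternatives for a table with the authors' statistics alone were not run, since no ERCC rows are listed and per-library values are. Depth limits low genes most: Il1b, at 8.42 normalized counts in wild type, lies close to the floor of 3 reads.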

Other observations

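The tests given here were chosen after the results they bear on were seen.

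Keratins, the filament proteins of epithelia, were higher in the libraries labelled Txn1 KO at low levels. Of 12 measured, with the pseudogene Krt8-ps (not called) among them, 8 rose and 0 fell (median log2 1.39; camera adjusted p = 1.10e-05, and adjusted p = 0.151 with an estimated correlation). Krt14 rose from 121.7 ± 49.1 to 349.3 ± 84.5 normalized counts and Krt5 from 76.0 ± 32.0 to 204.6 ± 54.2 (SD, n = 3 each; limma adjusted p = 2.72e-05 and 1.80e-04). The 4 measured Ugt1a genes, which conjugate glucuronic acid to drugs and bilirubin and share most of their exons, so that reads cannot be assigned with certainty, all rose (median 1.43; camera adjusted p = 3.50e-06, and adjusted p = 0.0269 with an estimated correlation). Ugt1a7c went from 1961 ± 67.3 to 3743 ± 154 normalized counts. All 8 Schlafen genes, with the pseudogene Slfn10-ps among them, fell (median -0.45; camera adjusted p = 3.96e-08, and adjusted p = 0.0651 with an estimated correlation). Several Schlafen genes respond to interferon. Slfn2 went from 17032 ± 1007 to 12740 ± 342 normalized counts.

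Genes of cytosolic ribosomal proteins and protein genes of mitochondrial DNA moved apart. Of 81 cytosolic ribosomal protein genes 50 fell and 1 rose, by a small amount (median log2 -0.14; camera adjusted p = 4.49e-16, and adjusted p = 0.180 with an estimated correlation). Of 13 protein genes of the mitochondrial genome 8 rose and 0 fell (median 0.49; camera adjusted p = 4.31e-09, and adjusted p = 0.0651 with an estimated correlation), with mt-Co1 at 179846 ± 3732 against 255253 ± 14539 normalized counts. Those not called (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd4l) had wild-type means of only 8.24 to 54.0 normalized counts. The lack of a call says little on these. The medians of the ribosomal and mitochondrial genes were -0.14 and 0.47 under TMM scaling and -0.13 and 0.48 under scaling on total reads. The median of all genes was -0.0049 in the main scaling, -0.0059 under TMM and 0.0017 on total reads. Scalings this close could not have changed the direction. Nnt, which carries a known deletion in C57BL/6J, rose in the libraries labelled Txn1 KO (log2 0.54).

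Txn1 was at 98.2% of wild type in the libraries labelled Txn1 KO. A wild-type library under a Txn1 KO label is argued against by Lyz2, whose highest level among the 3 was 1.19% of the wild-type mean. A deletion that leaves most Txn1 reads countable stays open, because the 98.2% is a sum over the whole gene and gives no value for any single exon. Txn1 left intact in most cells, with Lyz2-Cre or the strain behind the other changes, may also account for the level: the lower end of the 95% interval was 93.0%, and without a library with Cre alone the 2 cannot be told apart. No biological explanation was tested.

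Genes with a change of at least 2-fold gathered on chromosome 1 between 80 and 90 Mb (GRCm38): 10 of 53 tested genes, against 2.23% of all placed genes (permutation p = 5e-04 over 255 bins, the smallest that 2000 draws can give). Sp110, Sp140, Gm17017, C130026I21Rik, A530040E14Rik and Glrp1 fell and Ugt1a6a, Ugt1a6b, Ugt1a9 and B3gnt7 rose. In the adjoining stretches 6 of 56 genes (70 to 80 Mb, 10.7%) and 4 of 51 (90 to 100 Mb, 7.84%) changed as much. Their unadjusted hypergeometric p was 0.00148 and 0.0266, and their permutation p over the same 255 bins was 0.156 and 0.974. These 2 stretches were picked as neighbours after the first was seen. That 1 change was counted in several members of the Sp100 or Ugt1a families stays open. Without both families, 2 large changes among 43 genes are left between 80 and 90 Mb (exact hypergeometric p = 0.240, one-sided). The 10 genes taken out, 8 of them with a large change, included A530040E14Rik, C130026I21Rik and Gm17017. These were counted as members although not named as such, and the p without that choice was not computed. A stretch of another strain's DNA stays open as well, since 18.9% of genes changed between 80 and 90 Mb and no sequence is at hand, and the genotype as the cause is untested.

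Of 139 genes within 10 Mb of Txn1 or Lyz2, both counted, 5 with Lyz2 among them changed at least 2-fold (3.60%; Fisher's exact p = 0.242, two-sided, against all placed genes farther away). The stretch of chromosome 4 between 50 and 60 Mb, which holds Txn1, had 3 such genes of 31 (9.68%). Its unadjusted hypergeometric p was 0.0311 and its permutation p over 255 bins was 0.989.

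Liver transcripts in wild-type replicate 1 and Txn1 KO library 3 may come from RNA or reads of a liver sample. Of 30 liver markers 21 were measured, and 95.2% of them (20) had these 2 libraries as the highest 2 of 6. The pair and the markers were chosen after liver genes were seen high in it. Only 1 of the 21 had a mean of at least 10 in the other 4 libraries, so most were listed because these 2 were high. The share therefore only describes the pattern, and the source stays open. The most abundant were Alb, at 642.9 and 580.0 normalized counts, and Rbp4, at 326.1 and 273.2. Depth is argued against, since the lower of these 2 libraries had 42.2 times the share of reads in those 20 markers of the highest other while depths differed 1.72-fold. The 20 markers had 2692 and 1862 reads in these 2 libraries and 41 to 76 in the other 4, and none of the 21 was called by limma. No biological explanation was tested.

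The real split of the 6 libraries gave 3001 called genes in limma, and the highest of the other 9 splits gave 0 (160 to 390 at an unadjusted p under 0.05, against 4513). It was the only 1 of 10 splits with as many, and 10 splits are too few for a share under 0.05.

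Amy1, an amylase gene, had 1636 normalized counts in wild-type replicate 3 and 5.74 to 22.4 in the other 5 libraries. Lyve1 and Plvap, endothelial genes, had 141.4 and 343.1 normalized counts in Txn1 KO library 1, against at most 6.70 and 53.6 in the others. Of 531 tested pseudogenes 3.20% rose at least 2-fold, against 1.44% of 12145 protein-coding genes. Falls of at least 2-fold made up 0.942% and 0.683%. Rises of any size were called in 23 of the pseudogenes and 1525 of the protein-coding genes, a lower share of the pseudogenes.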
